A study of Mus musculus with 72 samples.

How the data were processed

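RNA was measured by sequencing in left cortex, left striatum and right cerebellum of male mice. The mice were wild type (wt) or carried 1 altered copy of Thap1 (Thap1+/-). They were naive or had received a crush of the right sciatic nerve, for 1 minute at 12 weeks of age, and were labelled as 12 weeks post injury. Each of the 3 tissues held 4 groups of 6 libraries, which made 72 libraries in all. Per the labels' protocols, 500 ng of total RNA went into each library with a stranded mRNA kit, and every library was sequenced a second time to add depth. RNA of the cerebellum was extracted with another kit than RNA of cortex and striatum, so the tissues were never compared directly in level.

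Counts per gene were deposited by the authors as whole numbers, with 1 column per library and 46320 genes of the GRCm39 build, per the file headers. The submitters' processing notes name cutadapt 4.6, STAR 2.7.2b, featureCounts 1.6.4 and DESeq2 in R 4.1.0, and these notes do not say how featureCounts treated strand. Genes that overlap an antisense partner or a near-identical copy are therefore uncertain. The log2 fold changes deposited by the authors came from DESeq2 comparisons of 2 groups at a time, per the file headers, with 4 tables for each tissue. The adjusted p-values of the authors stand beside them, also per the file headers. The 288 columns of normalized values in these tables were not used here. The count columns of the 4 tables of a tissue were checked against each other and held no differing value. The columns name the mutant group by the dystonia that goes with THAP1, and this group was taken as the one labelled Thap1+/-.

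Column names end in numbers that are not the replicate numbers of the labels, so a column was assigned to its group only. Libraries are called library 1 to 6 within a group in column order. The same 24 column numbers recur in each tissue with the same group, so library n of a group carries the same number in cortex, striatum and cerebellum. The labels do not say that a number stands for a mouse, but the 3 tissues were not treated as independent of each other. While the data were explored, edgeR was also run with the number ending each column name as a covariate, as a rank and as a split at the median. The genes called for injury in cerebellum came to 239 with the rank and 485 with the split, in place of 717. Neither was made the reported fit, because the labels do not say what those numbers stand for.

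Testing used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and statmod 1.5.0, and drawing used Python 3.11.15 with matplotlib 3.10.9. In each tissue the 24 libraries were fitted together with 1 mean per group, TMM factors and edgeR's filter on low counts. The quasi-likelihood test of edgeR was applied to 7 contrasts. These were the genotype effect in naive and in injured mice, the injury effect in wt and in Thap1+/- mice, the average of each pair, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the contrast. Levels per library are given as CPM, counts per megacount of the library after TMM scaling, and a log2 fold change is given with its standard error (SE).

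Before the data were examined, 30 pathway lists and 15 cell type lists of genes were written down. Of these 45 lists, 44 had members among the tested genes; the list of transcripts encoded in mitochondrial DNA had none and is not analysed here. The lists were tested with camera on voom values at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. The mean score of a list is its mean centred log2 CPM in a library; after the data were seen, each library was left out in turn from the difference in mean score of the lists described as higher or lower. The genes named in the text were fixed by a rule in advance. In each contrast these were the 8 highest and the 8 lowest log2 fold changes among called genes with a gene symbol and a mean of at least 1 CPM. Added to them were Thap1, up to 4 called members of each list, and, where fewer than 5 genes were called, the 5 genes with the smallest p.

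Alternatives planned before the data were examined were DESeq2, RLE factors, no filter on low counts, a fit of only the libraries compared, 2 surrogate variables, and a count without genes within 10 Mb of Thap1. Alternatives added after seeing the data were a correction for GC content and gene length, fits without libraries of doubt, leaving out each cerebellum library in turn, and the covariates from column numbers. The correction removed from every library a smooth trend of log2 CPM on GC content and exon length, with 5 degrees of freedom each. GC content came from GENCODE transcripts of the earlier mouse build, matched by gene symbol for 91.7% of tested genes in cortex, 91.6% in striatum and 91.8% in cerebellum, and no coordinate was taken from that build.

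The edgeR fit was tested on simulated counts with 200 genes changed in the injured groups, drawn from the means, library sizes and dispersions of each tissue. The changed genes had a mean above 1 CPM, and each gene was drawn independently of the others. The simulation thus holds no trend shared by the genes of a library, so its recovery and false calls need not carry over to the real libraries. For the averaged injury effect in cerebellum, edgeR recovered 34 of 50 genes changed 1.25-fold, 46 of 50 changed 1.5-fold, and 50 of 50 changed 2-fold. Of its 189 calls over 18347 genes 9 were false. For the averaged injury effect the 1.25-fold changes were recovered in 41 of 50 genes in cortex, over 17713 genes, and in 41 of 50 in striatum, over 17914 genes. For the injury effect in wt cerebellum the recovery at 1.25-fold was 23 of 50. Single values in groups of 6 were compared with exact permutation tests, and 12 against 12 libraries with 100000 permutations, all two-sided. Intervals given at 95% cover counting error only.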

Results

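Counts of RNA per gene were compared in 72 libraries, 24 from each of left cortex, left striatum and right cerebellum, with 6 libraries in each of the 4 groups of a tissue. Total counts per library ranged from 16942036 to 21876184 in cortex, from 16627899 to 22936265 in striatum and from 16639731 to 24188074 in cerebellum. In wt cortex the injured libraries were shallower than the naive ones, with totals of 17.96 ± 0.82 against 20.09 ± 0.98 M counts, where M is the prefix mega (SD, n = 6, exact permutation p = 0.00216). In cerebellum the mean was 20.06 M counts in 12 injured and 20.51 M counts in 12 naive libraries (permutation p = 0.605).

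Thap1 (identifier gene-Thap1, chromosome 8, 26648197 to 26654179, plus strand, GRCm39) was higher, not lower, in the libraries labelled Thap1+/-. In cortex the level was 9.51 ± 0.975 CPM in wt naive and 14.5 ± 1.77 CPM in Thap1+/- naive libraries, and 9.59 ± 1.25 against 15.2 ± 1.55 CPM in injured ones (SD, n = 6). Striatum gave 11.2 ± 1.35 against 17.4 ± 1.36 CPM in naive and 10.9 ± 0.54 against 18.5 ± 1.54 CPM in injured libraries. Cerebellum gave 10.6 ± 2.71 against 15.3 ± 2.72 CPM in naive and 9.42 ± 0.525 against 17.6 ± 0.789 CPM in injured libraries. These levels rest on 126 to 440 counts per library. A count over the whole gene takes in exons that the alteration may leave in place, so it does not measure the working transcript, and directions below are those of libraries labelled Thap1+/-.

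**Figure D1:**
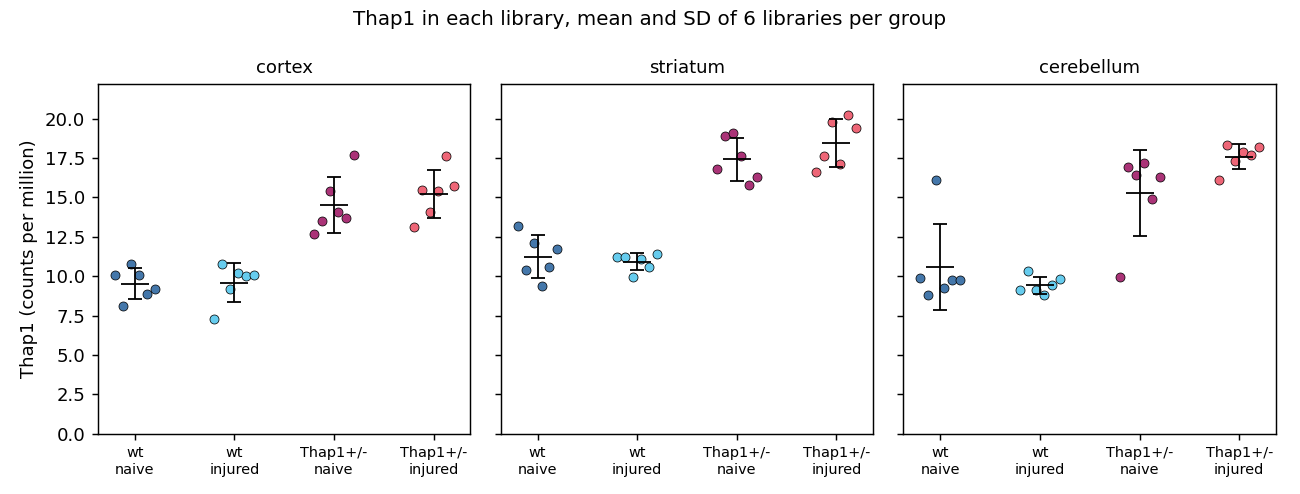
Thap1 in CPM (y axis) in each library (points) of the 4 groups (x axis) of each tissue, with the mean and SD of 6 libraries. Libraries labelled Thap1+/- lie above wt ones except in naive cerebellum, where 1 wt library stands at 16.1 CPM and 1 Thap1+/- library at 9.98 CPM.

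The first comparison asked what the Thap1 genotype changes in each tissue. Averaged over naive and injured mice, Thap1 rose in the libraries labelled Thap1+/- by a log2 fold change of 0.64 ± 0.07 in cortex (SE, 12 against 12 libraries, edgeR adjusted p = 7.48e-06). The same change was 0.70 ± 0.05 in striatum (adjusted p = 1.36e-08) and 0.72 ± 0.09 in cerebellum (adjusted p = 0.000267). It was seen in 12 of 12 libraries in cortex, 12 of 12 in striatum and 11 of 12 in cerebellum, counted against the wt mean. Beside Thap1, Snrnp35 (chromosome 5), which encodes a protein of the minor spliceosome, rose in cortex by 0.38 ± 0.05 (adjusted p = 0.000457) and in striatum by 0.30 ± 0.04 (adjusted p = 0.00226). In cortex Snrnp35 stood at 14.8 ± 1.06 CPM against 11.3 ± 1.11 CPM, and 11 of 12 libraries labelled Thap1+/- exceeded every wt library. Snrnp35 and Thap1 were the genes called upward in both cortex and striatum, whose libraries carry the same column numbers, so that the 2 tissues were not taken as independent.

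Striatum had 3 further calls for genotype. Ppp2r3c (chromosome 12) rose by 0.21 ± 0.04, from 14.7 ± 0.842 to 17.1 ± 0.584 CPM (edgeR adjusted p = 0.0164). Gusb (chromosome 5), which encodes the lysosomal enzyme beta-glucuronidase, fell by 0.30 on the log2 scale, from 13.4 ± 1.33 to 10.9 ± 1.06 CPM (adjusted p = 0.0345). Ppil3 (chromosome 1) fell by 0.27, from 11.6 ± 0.772 to 9.7 ± 0.822 CPM (adjusted p = 0.0184). All 3 showed their direction in 12 of 12 libraries against the wt mean. Without the filter on low counts these 3 genes missed the threshold, with adjusted p of 0.0543 for Ppp2r3c and 0.0805 for both Gusb and Ppil3, and the GC correction took Gusb to 0.0778. Without 1 Thap1+/- naive library with high hypothalamus and thalamus markers, the adjusted p of Gusb was 0.0556. Gusb in that library, at 11.8 CPM, lay above the Thap1+/- mean of 10.9 CPM, so the fall did not rest on its value.

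Snrnp35 in cerebellum, Gusb in cortex and cerebellum, and Ppil3 in cortex were not called by edgeR but had fold changes of like size. Ppil3 in cerebellum and Ppp2r3c outside striatum are not compared here. Shld1, Cyb5d2 and Arsk, given beside them, were not called for genotype by edgeR in any tissue. In cortex the log2 fold change was -0.28 ± 0.06 for Gusb, -0.24 ± 0.05 for Ppil3 and -0.35 ± 0.07 for Shld1, with an edgeR adjusted p of 0.16 for each. In cerebellum it was 0.29 ± 0.05 for Snrnp35 (adjusted p = 0.133), and for Cyb5d2, Arsk and Gusb it was 0.21 ± 0.05, 0.20 ± 0.04 and -0.32 ± 0.07 (adjusted p = 0.6 for each). Without the 2 cerebellum libraries whose Thap1 lay in the range of the other genotype, a choice made after seeing the data, edgeR called Snrnp35 at 0.32 (adjusted p = 0.00308) and Gusb at -0.40 (adjusted p = 0.000874).

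**Figure D2:**
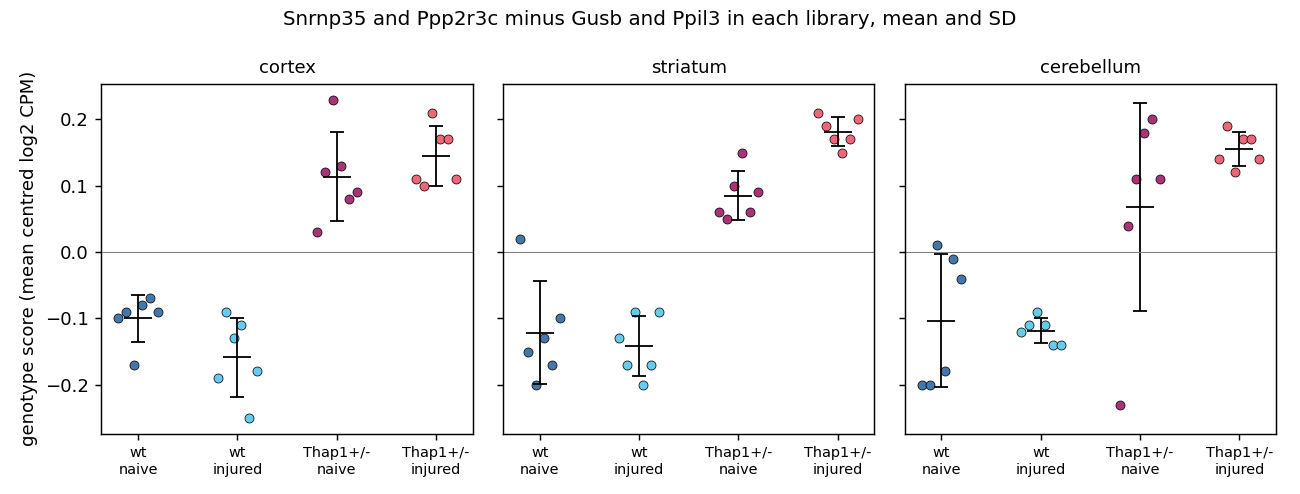
Mean centred log2 CPM of Snrnp35 and Ppp2r3c with the sign-reversed values of Gusb and Ppil3 (y axis) in each library (points) of the 4 groups (x axis), with the mean and SD of 6 libraries. The genes were called in cortex or striatum, so the cerebellum panel is the one they were not chosen on. Its libraries carry the same column numbers as those tissues, so this panel was not taken as independent of them. There the out-of-place Thap1+/- naive library stands at -0.23.

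By state, edgeR called Thap1 alone in naive cortex (log2 fold change 0.61 ± 0.09, adjusted p = 0.0105), naive striatum (0.63 ± 0.07, adjusted p = 0.000125), injured striatum (0.76 ± 0.07, adjusted p = 3.49e-06) and injured cerebellum (0.90 ± 0.12, adjusted p = 0.00242). Injured cortex gave Thap1 at 0.67 ± 0.09 (adjusted p = 0.00268) and Snrnp35 at 0.47 ± 0.07 (adjusted p = 0.00616). In naive cerebellum edgeR called 0 genes, with 1117 at an unadjusted p under 0.05, and DESeq2 also called 0. Thap1 stood there at 0.54 ± 0.12 (edgeR adjusted p = 0.818). Without the 2 libraries whose Thap1 lay in the range of the other genotype it was 0.78 ± 0.06. That choice is circular for Thap1, as the 2 were chosen by it. None of the 118 genes within 10 Mb of Thap1 tested in cortex, 116 in striatum and 122 in cerebellum was called for the averaged genotype effect (Fisher's exact p = 1 in each). Of these, 1, 4 and 2 had an unadjusted p under 0.05. Among genes further away only 1, 4 and 0 were called, so Fisher's test says little here, and in cerebellum it could give no other value. The 17 or 18 measured genes of the list of YY1 and reported THAP1 targets showed no common shift, with median log2 fold changes of 0.00 in cortex, -0.00 in striatum and -0.00 in cerebellum. The immediate early genes were higher in libraries labelled Thap1+/- by a median of 0.20 in cortex, 0.21 in striatum and 0.21 in cerebellum by camera at the preset correlation (adjusted p = 1.28e-05, 1.34e-08 and 0.000165). None of these list calls held with an estimated correlation (adjusted p = 0.885, 0.52 and 0.719), and no member passed the threshold. In cortex the difference in their mean score went from 0.20 to 0.13 without Thap1+/- naive library 2. For genotype the authors' tables list 1 gene higher in naive and 2 in injured cortex, 3 higher in naive striatum, 2 higher and 1 lower in injured striatum, 0 in naive cerebellum and 2 higher in injured cerebellum.

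The second comparison asked what remains changed in the brain 12 weeks after the sciatic nerve crush. In cerebellum, averaged over both genotypes, 333 genes rose and 384 fell (edgeR, 717 of 18461 genes, 12 against 12 libraries), with a median absolute log2 fold change of 0.154. Leaving out 1 library, a choice made after seeing the data, moved this count to between 202 genes, without wt injured library 4, and 1290, without wt naive library 5. Ppef2 rose by 0.51 ± 0.14 (adjusted p = 0.0404), Scel by 0.41 ± 0.10 (adjusted p = 0.0243) and Akr1c14 by 0.37 ± 0.10 (adjusted p = 0.043). Chrna2, which encodes a nicotinic acetylcholine receptor subunit, fell by 0.67 on the log2 scale, from 1.39 ± 0.4 to 0.875 ± 0.292 CPM (adjusted p = 0.0408). Castor1 fell by 0.52 (adjusted p = 0.0334), Evpl by 0.50 (adjusted p = 0.0366) and Abcc6 by 0.47 (adjusted p = 0.0493). The kinase gene Clk1, at 133 ± 17.2 CPM in naive libraries, rose to 162 ± 25.5 CPM, and Brwd3 rose from 28.8 ± 2.46 to 34.4 ± 3.38 CPM. Zfp975, Zbtb44 and Ppwd1 rose by 0.33, 0.28 and 0.26, while Fcrlb, Vsig10l, Rps27rt and Tfr2 fell by 0.45, 0.45, 0.40 and 0.38. Rps27rt is a near-identical copy of a ribosomal protein gene, so its reads are uncertain.

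In injured cerebellum 32 of 36 complex I subunits were lower, with a median log2 fold change of -0.08; 9 fell by the test over all genes and 18 adjusted over the list alone. Ndufs7, Ndufa11 and Ndufa2 each fell by 0.17 (edgeR adjusted p = 0.0142 for each) and Ndufc1 by 0.16 (adjusted p = 0.0317). With the GC and length correction, under which no called gene stayed called, they stood at -0.06, -0.10, -0.12 and -0.16. Of 17 ATP synthase subunits 16 were lower and 5 fell, among them Atp5e by 0.19 (adjusted p = 0.0152), Atp5d by 0.15 (adjusted p = 0.00927), Atp5g1 by 0.13 and Atp5g2 by 0.11. Corrected, the named ones stood at -0.15, -0.06, -0.12 and 0.03. Uqcrq, Uqcrc1, Cox6a1 and Cox8a fell by 0.15, 0.11, 0.14 and 0.13 (corrected -0.12, -0.06, 0.00 and -0.02). In central carbon metabolism Pcx, Mpc2, Gpi1 and Aldoa fell by 0.15, 0.14, 0.11 and 0.10 (corrected -0.09, -0.15, -0.09 and -0.03). Of 74 cytosolic ribosome genes 67 were lower and 9 fell, with 21 adjusted over the list alone, and Rps21 fell by 0.19 (adjusted p = 0.0203, corrected log2 fold change -0.14). Camera at the preset correlation gave an adjusted p of 1.77e-12 for complex I, 8.2e-06 for ATP synthase and 4.56e-11 for the cytosolic ribosome. These camera values were taken without the GC and length correction. They do not separate a shift of these lists from the trend that the correction removes. None of these list calls held with an estimated correlation (adjusted p = 0.701 for each). Fry, which tests a list by itself and not against other genes, gave 0.0266 for complex I. Gabpa, which encodes a transcription factor of nuclear genes for mitochondria, rose by 0.21 ± 0.04 (edgeR adjusted p = 0.00927), and by 0.14 with the GC and length correction.

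Single members of further lists fell in injured cerebellum. The GABA signalling list was split at 11 higher and 10 lower genes, and the difference in mean score of the cholinergic signalling list, -0.13, rested on single libraries, at -0.08 without wt injured library 3 or without wt naive library 1. Slc32a1, which encodes the vesicular GABA transporter, fell by 0.20 (edgeR adjusted p = 0.00927), Ache by 0.25 (adjusted p = 0.021), Grin2d by 0.24 (adjusted p = 0.0408), Hcn2 by 0.19 (adjusted p = 0.0344) and Rab3a by 0.11 (adjusted p = 0.023). With the GC and length correction these log2 fold changes were -0.11, -0.18, -0.14, -0.07 and -0.05, in the same order. Olig1, Bcan, Cldn5, Pltp and Mt1 fell by 0.30, 0.17, 0.18, 0.12 and 0.21. Their corrected values were -0.19, -0.10, -0.07, -0.04 and -0.16. Cerebellum wt naive library 1 had the lowest cerebellar neuron score (-0.95) and high oligodendrocyte and microglia scores (0.51 and 0.50); without it Pltp was no longer past the threshold (-0.10, adjusted p = 0.0672) and the others were. The dystonia gene Pnkd fell by 0.17 (adjusted p = 0.0334), as did Map1lc3a by 0.15, Map1lc3b by 0.11 and Mrps24 by 0.19. The Y-linked Uty rose by 0.15 (adjusted p = 0.0211). Corrected for GC content and length, Pnkd stood at -0.19, Map1lc3a at -0.02, Map1lc3b at -0.09, Mrps24 at -0.11 and Uty at 0.04. The unfolded protein response and heat shock list was higher in 27 of 28 genes, with a median of 0.15 and a camera adjusted p of 8.11e-05, which did not hold with an estimated correlation (adjusted p = 0.701). No member of that list passed the threshold, and the difference in its mean score went from 0.15 to 0.10 without wt injured library 2.

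Many of these cerebellar changes, though not all, went with the GC content of the genes. The genes that rose had a median GC content of 40.8% and those that fell 57.2%, against 49.7% over tested genes, for 96.5% of the called genes with a value. Median exon length was 6161 bases in genes that rose and 2025 bases in genes that fell. Within each library the correlation across genes of relative expression with GC content averaged -0.165 ± 0.145 in injured and 0.177 ± 0.145 in naive cerebellum (SD, n = 12, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 3e-05 over the 3 tissues). It held within wt libraries (-0.121 against 0.161, n = 6, exact permutation p = 0.013) and within Thap1+/- libraries (-0.208 against 0.194, n = 6, exact permutation p = 0.00216). Pooled over genotypes, no difference in this measure was detected in cortex or striatum (permutation p = 0.456 and 0.282). In cortex the genotypes went opposite ways, with a difference of -0.079 in wt (n = 6, exact permutation p = 0.541) and 0.200 in Thap1+/- libraries (n = 6, exact permutation p = 0.0519); in striatum they were 0.053 and 0.102. After each library's trend on GC content and length was removed, a step chosen after seeing the data, edgeR called 0 genes for injury in cerebellum (2017 at an unadjusted p under 0.05, smallest adjusted p = 0.0504). The median absolute log2 fold change of the 717 genes went from 0.15 to 0.08 with a median SE of 0.037 before and 0.034 after, and 705 kept their direction. Of the 717 genes 684 had a smaller fold after the correction, such as Ndufs7 and Atp5d, both at -0.06, and Cldn5 at -0.07. Cox6a1 and Atp5g2 went from -0.14 and -0.11 to 0.00 and 0.03. Less moved were Ndufc1, which stayed at -0.16, Mpc2 (-0.14 to -0.15), Pnkd (-0.17 to -0.19), Ppef2 (0.51 to 0.52) and Chrna2 (-0.67 to -0.66). Ndufc1 and Mpc2 fell with a GC content of 44.1% and 43.2%, below that of tested genes.

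**Figure D3:**
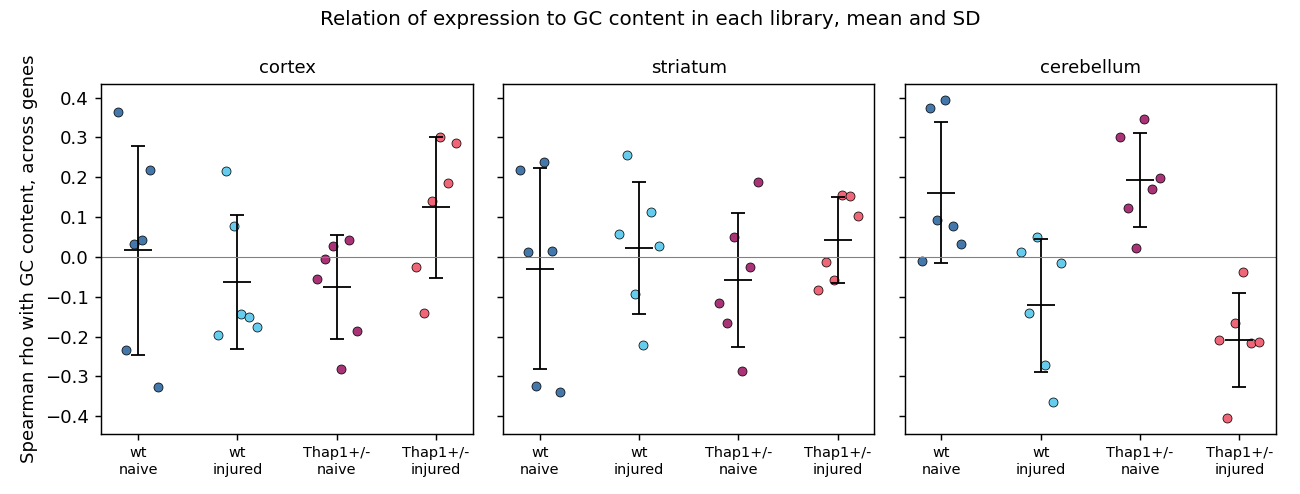
Spearman correlation across genes between relative expression and GC content (y axis) in each library (points) of the 4 groups (x axis), with the mean and SD of 6 libraries. In cerebellum the injured libraries average -0.165 and the naive ones 0.177; genes are not independent replicates.

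**Figure D4:**
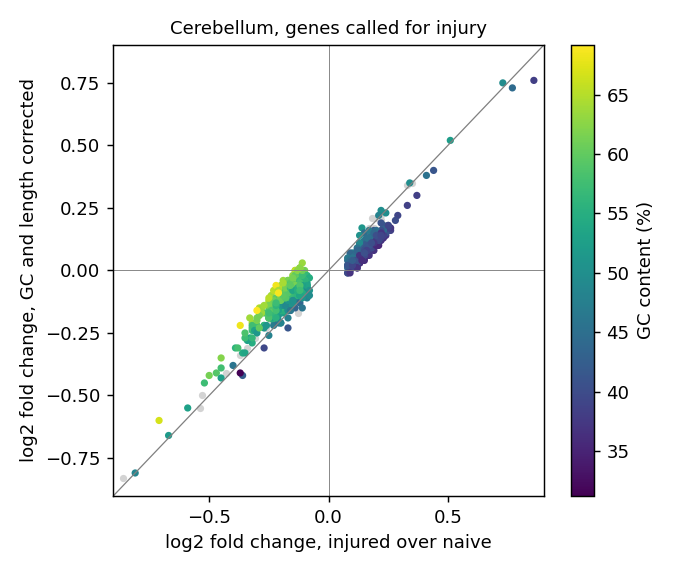
Log2 fold change of injured over naive cerebellum for the 717 called genes before (x axis) and after (y axis) removal of each library's trend on GC content and exon length, coloured by GC content in percent, grey where it is unknown. Points on the diagonal are unmoved; 684 of the 717 genes moved toward 0.

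Taken by genotype, injury called 0 genes in wt cerebellum by edgeR (3641 at an unadjusted p under 0.05), while DESeq2 called 818. The genes with the smallest p were Srebf1 (-0.34 ± 0.06), Entpd6 (-0.24 ± 0.05), Rbm41 (0.41 ± 0.08), Trip11 (0.16 ± 0.03) and Fgd4 (0.38 ± 0.07), each with an edgeR adjusted p of 0.0558. In Thap1+/- cerebellum edgeR called 0 genes (1852 at an unadjusted p under 0.05) and DESeq2 called 49, and Bmyc (-0.28 ± 0.05), B4galt7, Ndufa2, Ppdpf and Abhd8 came first with an edgeR adjusted p of 0.169. The authors' own tables list 393 genes higher and 322 lower with injury in wt cerebellum, and 5 higher and 27 lower in Thap1+/- cerebellum, at an adjusted p under 0.05.

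In wt cortex the genes with the smallest p for injury were Nid1, Dok6, Slc13a3, Dbpht2 and Them6. Their log2 fold changes were 0.54 ± 0.09, 0.24 ± 0.05, 0.48 ± 0.09, 0.28 ± 0.05 and -0.26 ± 0.05 (edgeR adjusted p = 0.0846 for each). EdgeR called 0 genes in this contrast (1513 at an unadjusted p under 0.05), while DESeq2 called 22, these 5 among them. DESeq2's calls included C4b at 0.83 (adjusted p = 0.0053), Fn1 at 0.41 (adjusted p = 0.0053) and Col1a2 at 0.58 (adjusted p = 0.0425), named here after their values were seen. The meninges and fibroblast list was higher in 14 of 16 genes by a median of 0.43, with 7 genes past the threshold adjusted over the list alone and a camera adjusted p of 6.17e-08, which did not hold with an estimated correlation (adjusted p = 0.352). Complex I subunits were lower in 35 of 36 genes by a median of -0.09 (camera adjusted p = 6.17e-08, and 0.652 with an estimated correlation), but the difference in their mean score went from -0.09 to -0.04 without wt injured library 4. The authors' tables list 18 genes higher and 4 lower in this contrast, and 0 in Thap1+/- cortex. In Thap1+/- cortex edgeR called 0 genes (455 at an unadjusted p under 0.05) and so did DESeq2, and averaged over genotypes both called 0 (edgeR, 921 at an unadjusted p under 0.05). Cdk20, St3gal6, Egfr, Ptprh and Atp4a came first in Thap1+/- cortex, and Ptprh (-0.42 ± 0.10), Nid1, Tmem64 and St3gal6 on average, with adjusted p of 1 and 0.911.

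In striatum injury called 0 genes in wt mice by edgeR (612 at an unadjusted p under 0.05) and by DESeq2. Dock8 came first, at 8.02 ± 0.387 CPM in naive and 10.4 ± 0.848 CPM in injured wt libraries (log2 fold change 0.38 ± 0.07, edgeR adjusted p = 0.184). In Thap1+/- striatum edgeR called 0 genes (1165 at an unadjusted p under 0.05) and DESeq2 called 2, Scd2 at -0.21 (adjusted p = 0.00548) and Shox2 at -5.55 (adjusted p = 5.12e-05). Shox2, a gene of the thalamus, stood at 13 and 13.6 CPM in Thap1+/- naive libraries 4 and 5 and at 4.73 CPM in library 3, against 0.755 CPM or less in all other striatum libraries. Libraries 4 and 5 were also high in hypothalamus and thalamus markers (scores 0.45 and 0.77), but library 3 was not (-0.03). Pcsk6, Mr1, Cebpd and Mid1ip1 followed at -0.26, -0.50, 0.78 and -0.22 (edgeR adjusted p = 0.715). All 24 oligodendrocyte and myelin genes were lower in injured Thap1+/- striatum, by a median of -0.25, with 18 past the threshold adjusted over the list alone. Camera gave an adjusted p of 1.23e-20 for this list, which did not hold with an estimated correlation (adjusted p = 0.411). Markers of other regions moved in the same contrast: hypothalamus and thalamus genes were lower by a median of -0.36, choroid plexus genes lower by -0.37 and cortical projection neuron genes higher by 0.66 (camera adjusted p = 0.000391, 0.000698 and 0.000391, each 0.411 with an estimated correlation). Without Thap1+/- naive library 5 the difference in mean score went from -0.30 to -0.19 for hypothalamus and thalamus genes and from 0.58 to 0.38 for cortical projection neuron genes. Averaged over genotypes edgeR called 0 genes (960 at an unadjusted p under 0.05) and DESeq2 called 0. The authors' tables list 0 genes for injury in wt striatum and 3 lower in Thap1+/- striatum.

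The third comparison asked whether injury acts differently in the 2 genotypes. The interaction called 0 genes by edgeR in cortex, striatum and cerebellum (986, 808 and 1426 at an unadjusted p under 0.05), and DESeq2 called 0 in each. In cortex the smallest p belonged to Egfr (-0.46 ± 0.10), Dbpht2 (-0.35 ± 0.08), Them6 (0.33 ± 0.07), Tmed5 (-0.33 ± 0.08) and Dok6 (-0.27 ± 0.06), with an edgeR adjusted p of 0.621. In striatum it belonged to Mr1, Cfap157 and Sting1 among genes with a plain symbol (adjusted p = 0.982), and in cerebellum to Krt1 (0.81 ± 0.20, adjusted p = 0.637). Thap1 gave 0.06 ± 0.13, 0.13 ± 0.10 and 0.36 ± 0.17 in cortex, striatum and cerebellum (adjusted p = 0.994, 0.982 and 0.638). The cerebellar value takes in the 2 naive libraries whose Thap1 lay in the range of the other genotype. Microglia genes gave a lower injury effect in Thap1+/- than in wt cortex in 19 of 20 genes, with a median of -0.18 (camera adjusted p = 2.28e-06, and 0.582 with an estimated correlation). This was not particular to microglia, as astrocyte genes were lower in 19 of 20 (median -0.15) and meninges and fibroblast genes in 14 of 16 (median -0.42), each 0.582 with an estimated correlation. The wt and Thap1+/- injury effects, which share no libraries, had a correlation across all genes of -0.00818 in cortex, 0.0186 in striatum and -0.0175 in cerebellum. Genes are not independent replicates. Every gene weighs alike in this correlation, also those with few counts, so it does not show that the genotypes respond differently. In cerebellum the correlation of expression with GC content moved the same way in both, by -0.282 in wt and -0.402 in Thap1+/- libraries (injured minus naive).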

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

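Dixon's test was run 80 times, once for each measure in each group of 6 libraries to which it applied, and in 8 of these 1 library lay far from the others, where chance alone picks about 1 in 20; the 8 measures tested were chosen after the data were seen, as were the tests of the Thap1 values below.

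Thap1 in cerebellum was 16.1 CPM in wt naive library 3, against 8.82 to 9.87 CPM in the other wt naive libraries, and 9.98 CPM in Thap1+/- naive library 1, against 14.9 to 17.2 CPM in the others. These values argue against counting error, since the lower 95% Poisson bound of the wt library is 14.3 CPM and the other 11 wt libraries end at 10.3 CPM. An exchange of these 2 labels stays open, as over Snrnp35, Ppp2r3c, Gusb and Ppil3, the library labelled Thap1+/- minus the one labelled wt gave -0.24: the first scored -0.23, below the other wt libraries (-0.20 to -0.01), but the library labelled wt scored 0.01, between these and the other Thap1+/- libraries (0.04 to 0.20), so this score places only the first with the other genotype. Over 205 other genes, 22 of 22 other cerebellum libraries correlated best with the cortex and striatum libraries of their own column number (r = 0.41 to 0.85 across genes, which are not independent replicates), while the library labelled wt had r = -0.10 with its own number and 0.84 with that of the other, and the one labelled Thap1+/- had r = -0.25 with its own and 0.42 with that of the other. The score thus may point to an exchange for the library labelled Thap1+/- and the match for the one labelled wt. Each test leaves the other library unclear, though neither library matched its own number best. Their r of -0.10 and -0.25 lay below the lowest of the other 22 libraries, 0.41. If a number stands for the same mouse in each tissue, this argues against the column numbers of both as given. It does not settle which libraries they are. The 0.42 of the library labelled Thap1+/- lay within the range of the others but was not its highest. The best match of the library labelled Thap1+/-, at 0.47, was Thap1+/- naive library 4. Both were kept as labelled, and no biological explanation was tested.

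The other 6 libraries were far from their group in depth or in a score of marker genes, given as mean centred log2 CPM. Striatum wt naive library 4 had 22936265 total counts, against 18411482 to 19760453 in the rest. The choroid plexus and ependyma score was 3.68 in cortex wt naive library 3 (others -0.68 to 0.23) and -1.25 in cerebellum wt injured library 3 (others -0.17 to 0.27). The striatal projection neuron score was 0.29 in striatum wt naive library 1 (others -0.03 to 0.02) and -0.64 in striatum wt injured library 6 (others -0.03 to 0.15). The oligodendrocyte and myelin score was -0.41 in cerebellum Thap1+/- naive library 5 (others -0.02 to 0.16). The cause was not tested for these 6.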

How the results depend on the processing

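The GC and length correction, the fits without libraries of doubt, the leave-one-out fits and the covariates from column numbers were chosen after the data were seen; the other alternatives were planned. Of 623 values of named genes under the alternatives, 621 kept their direction and 422 their side of the threshold, while 198 kept their direction but were no longer past it and 1 was newly past it. The 2 that changed direction and were also no longer past it, both under the GC and length correction of the cerebellar injury effect, were Cox6a1 at 0.00 and Atp5g2 at 0.03. Thap1 aside, these genes were included because they were called in the same counts, so a kept direction was likely from the start.

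DESeq2 called more genes than edgeR in 10 contrasts. For genotype it called 4 genes in cortex (adding Shld1 and Gusb, both lower) and 11 in striatum on average, 3 in injured striatum, and 2 in cerebellum (Thap1 and Snrnp35) both on average and after injury. For injury it called 22 genes in wt cortex, 2 in Thap1+/- striatum, 818 in wt cerebellum, 49 in Thap1+/- cerebellum and 1275 in cerebellum on average, with 677 of edgeR's 717 among them. With 2 surrogate variables 19 genes were called for injury in wt cortex and 57 in Thap1+/- cerebellum, and for genotype 2 in injured striatum, 10 in striatum on average and 3 in cortex on average, Ppil3 added. The averaged injury effect in cerebellum then gave 497 genes, of which 244 were among the 717. With the rank of the column number as a covariate that effect gave 239 genes, 231 of them among the 717, and injury in wt cortex 1. With column numbers above and below their median it gave 485, 465 of them among the 717, and genotype in naive cortex gave 0 by edgeR (567 at an unadjusted p under 0.05). The cause was not tested.

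Without the filter on low counts 1 gene, Shox2, was called for injury in Thap1+/- striatum, 2 for genotype in striatum and 186 for injury in cerebellum, all 186 among the 717; more genes were then tested. With only the libraries compared, edgeR called 0 genes for genotype in naive cortex (684 at an unadjusted p under 0.05) and 0 in injured cortex (530), where Thap1 had adjusted p of 0.0538 and 0.0598, and DESeq2 on 24 libraries called 1 and 2. The same fit called 2 genes in injured striatum and 3 in injured cerebellum; it rests on fewer libraries.

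Without the 2 naive cerebellum libraries with Thap1 in the range of the other genotype, genotype called 1 gene in naive mice, 2 in injured mice and 3 on average. For Thap1 this is circular, as the 2 were chosen by it. The GC and length correction left 0 of the 717 genes called for injury in cerebellum by edgeR (2017 at an unadjusted p under 0.05), because the folds shrank while their SE did not grow. Leaving out each cerebellum library in turn gave 202 to 1290 genes. The count moved by over 1.5 times without wt injured library 4 (202), 5 (302) or 6 (359), Thap1+/- injured library 3 (406) or 6 (250), Thap1+/- naive library 1 (375), 4 (372) or 6 (333), or wt naive library 2 (267), 4 (279) or 5 (1290).

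Gene lists past the threshold of camera at the preset correlation came to 0 in all 21 contrasts with an estimated correlation. By fry, 1 list passed for injury in wt cortex, 1 in wt cerebellum and 2 in cerebellum on average, and 0 in the other 18 contrasts. No paired analysis was possible because the columns carry no replicate numbers of the labels, and within a tissue no column number occurs in more than 1 of the groups compared; no contrast compares tissues. In the simulation, which holds no trend shared by the genes of a library, a change of 1.25-fold in wt cerebellum was recovered for 23 of 50 genes.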

Other observations

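The tests of depth, of genes near Thap1 and of single libraries were chosen after the result was seen. The test of the GC correction was set before its result, though the GC trend of each library had been seen; an added condition on the kept fold, which would have left the matter open, was added after the result and withdrawn.

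The injury effect in cerebellum may be in large part a trend on GC content and length, since 0 of the 717 genes stayed called after its removal. A difference in depth is argued against by the permutation p of 0.605 for total counts and a mean difference of -2.21%. The fold was not removed whole, as the median share of its log2 fold change that a gene kept was 54.7%. After the correction 705 genes kept their direction and 456 had an unadjusted p under 0.05. The labels give no library date or RNA quality, so whether the trend came from the handling of the groups or from injury itself stays open. Apart from the trend, edgeR called 0 genes for injury (2017 at an unadjusted p under 0.05, smallest adjusted p = 0.0504), and 55 genes had an adjusted p under 0.1, 43 of them among the 717.

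Thap1 was higher in libraries labelled Thap1+/-, and a GC or length trend is argued against by corrected log2 fold changes of 0.65 in cortex, 0.70 in striatum and 0.70 in cerebellum. A stretch of chromosome from another strain cannot be told apart from an effect of the allele, since 0 genes within 10 Mb were called by edgeR (1, 4 and 2 at an unadjusted p under 0.05) and linked variants need not change their levels. Counts per gene hold no exons, so a transcript from the altered allele that is still counted was not tested. An exchange of the genotype names of the columns throughout would reverse every genotype direction given, and it was not tested either.

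Each contrast was compared with 100 splits of the same libraries, the real one included. For genotype, few splits reached the real count in naive cortex (1 gene, 1 split, highest other 0). The same held in cortex on average (2 genes, 2 splits, highest other 2) and naive striatum (1 gene, 2 splits, highest other 1). Striatum on average was alike (5 genes, 3 splits, highest other 86). Few splits also reached the real count in injured cerebellum (1 gene, 3 splits, highest other 5) and cerebellum on average (1 gene, 3 splits, highest other 742). Chance cannot be excluded by this count in injured cortex (2 genes, 6 splits, highest other 621) and injured striatum (1 gene, 11 splits, highest other 404). The injury effect in cerebellum on average, 717 genes, was reached by 1 split, the real one, with 2 genes as the highest other. This argues against chance for the number of genes, but not against a trend that goes with the groups. Where edgeR called 0 genes, all 100 splits reach that count by definition, so chance was not tested there. The highest other split called 748 genes in naive cerebellum, and 69 in cortex, 9 in striatum and 19 in cerebellum for the interaction. For injury the highest other split called 981 genes in wt, 0 in Thap1+/- and 2 on average in cortex. These counts were 3, 120 and 40 in striatum and, by genotype, 363 and 0 in cerebellum. The median count of the other splits was 0 genes in each contrast. Why some splits called far more genes than the real one was not tested.

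For the number of gene lists past the threshold, chance cannot be excluded in any of the 21 contrasts. The splits only counted lists, so they judge no single list. In cortex as many lists passed in 26 splits for genotype in naive mice (16 lists, highest other 23), 67 in injured mice (11, 25) and 76 on average (8, 27), and for injury in 57 in wt (15, 28), 64 in Thap1+/- (6, 16), 32 on average (16, 22) and 66 for the interaction (11, 24). In striatum the splits were 68 (9 lists, highest other 25), 24 (15, 22) and 72 (9, 22) for genotype, and 88 (7, 19), 52 (12, 24), 48 (11, 19) and 65 (10, 19) for injury and the interaction, in the same order. In cerebellum they were 79 (9, 29), 23 (18, 24) and 69 (10, 27) for genotype, and 25 (20, 28), 41 (10, 23), 39 (14, 25) and 90 (7, 27) for injury and the interaction.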
